A study of Microcystis aeruginosa KW with 2 samples.

How the data were processed

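RNA of 2 morphotypes of Microcystis aeruginosa KW, S-type and W-type, was sequenced as 1 library each. Per the labels' protocols, total RNA was depleted of ribosomal RNA with a Ribo-Zero kit for bacteria and made into libraries with the TruSeq RNA Sample Prep Kit v2, a kit that does not mark strand. The aligner, the counting tool, the genome build, the handling of strand and of reads that fit several loci are not given in the sources used here. Values of loci that overlap or have near-identical copies are uncertain for that reason.

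Each deposited table holds, per the file headers, whole-number read counts per locus and an RPKM value (reads scaled by gene length and by a read total) that the authors computed. The total behind the RPKM is not stated in the headers. It was recovered here from the division of count by RPKM at abundant loci (over 2000 counts and an RPKM over 100, 356 loci in the S-type and 393 in the W-type), as the largest total for which every one of these loci had a whole length within 0.06 nt. It came to about 18537594 reads in the S-type and 19668142 in the W-type, more than the summed counts of 8291347 and 12106871. As RPKM values are rounded, these totals and numbers derived from them are not exact to the single read. With these totals, exactly 1 whole length fitted the RPKM values of both libraries, each within 0.0051 for rounding to 2 decimals, at 4459 of 4987 loci (89.4%). Of these lengths 96.4% were multiples of 3, so lengths are called coding lengths. At the other loci the middle of the fitting range was used. They are inferred and were not read from an annotation. All columns of per-sample values in the tables were used, the RPKM columns for lengths, for the totals and as an alternative scale.

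The analysis was computed from the counts. Loci with a sum of at least 20 reads over both libraries entered the comparison, which left out 808 loci with 0.025% of the counts. Counts were scaled to CPM with edgeR 4.0.16 TMM factors (0.994 for the S-type and 1.006 for the W-type) in R 4.3.3, and the fold was log2 of W-type over S-type after adding 1 CPM, which understates the fold of low loci. Ratios given for single loci and runs carry no pseudocount, except the range over the single loci of 1 run, where this is stated. Where a ratio has an interval, it is an exact 95% conditional binomial (Clopper-Pearson) interval. Shares of counts have 95% Wilson intervals. Reads are not independent molecules where PCR copied them, so all intervals cover counting error only. A count of 0 allows up to 3 counts, which is 0.364 CPM in the S-type and 0.246 CPM in the W-type. With 1 library per group no dispersion can be estimated, so no test and no p-value is given, and a 2-fold size rule is used instead.

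The comparison, filter, pseudocount and size rule were chosen before the data were examined, as were the alternatives below other than the RPKM scale, the centred scales and those for runs. So was the rule for named loci. It took, with no names paired to the tags, the 2 loci with the largest fold in each direction. Its part on the 5 most abundant loci is followed by rank and without tags. In the same step 39 gene lists were fixed by symbol and product. None could be matched to locus tags, so no list has a result. Runs of neighbouring loci, length classes and the RPKM scale were chosen after the counts had been seen, and the single runs and the locus of 462 nt described in the text were singled out by their values. Neighbours are loci whose tag numbers differ by 5; borders between contigs are not known. Runs were compared with 1000 random orders of the folds. Length classes were compared with 10000 random lists matched within 10 bins of level.

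Alternatives were pseudocounts of 0.1 and 10 CPM, no filter and a minimum of 100 reads, DESeq2 1.42.0 median-of-ratios factors, upper-quartile scaling, plain totals, totals without the 10 most abundant loci, a 4-fold size rule, the deposited RPKM, the RPKM and the totals without the 10 loci each centred on their median, and runs of at least 3 loci or with a 4-fold rule. The calculations were tested on simulated data with Poisson counting error for this comparison. Loci with under 20 simulated reads were left out before scoring, so the shares cover only the loci that remained. Of 78 remaining loci with a 2.83-fold change 91.0% were found beyond 2-fold in the right direction. Of 78 with a 4-fold change 98.7% were so found, as were all 36 remaining loci with an 8-fold change. Over these 192 changed loci, 97.4% of the intervals held the simulated fold. All 30 loci of simulated runs were recovered. These runs were built from well-covered loci with a 4-fold change, so this does not test runs of quiet loci or runs near 2-fold. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.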

Results

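Transcript levels were measured by RNA sequencing in 2 libraries of Microcystis aeruginosa strain KW, a freshwater cyanobacterium of a species that forms surface blooms. One library came from the smooth S-type and one from the wrinkled W-type, morphotypes that appeared without treatment in still laboratory cultures of the strain. The comparison asks which transcripts differ between the forms. The tables list 5795 loci by locus tag, with a read count and an RPKM value for each library. The S-type library held 8291347 counts, with a median of 171 per locus, and the W-type library held 12106871 counts, with a median of 243. At least 10 reads were counted at 4899 loci in the S-type and at 5033 loci in the W-type. The tables pair the locus tags with neither gene names nor products nor coordinates, so loci are described by tag, by coding length and by their order along the tags, and no function is assigned to them. There was 1 library per morphotype, so no difference below has a replicate check, and intervals cover counting error only.

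Most loci lay at similar levels in the W-type and S-type libraries, and among those that differed more were lower in the W-type. Of 4987 loci with at least 20 reads over both libraries, 4324 (86.7%) lay within 2-fold, 171 (3.43%) were at least 2-fold higher in the W-type and 492 (9.87%) were at least 2-fold lower, on TMM-scaled read counts (CPM, the counts scaled to a common library total) with a pseudocount of 1 CPM. At least 8-fold differences were found at 6 loci higher and 20 loci lower in the W-type. The 95% counting interval lay wholly beyond 2-fold at 84 of the higher and 346 of the lower loci. In simulated libraries of the same depth with no change, counting error alone put 2 loci 2-fold higher and 0 loci 2-fold lower. Across loci, CPM values of both libraries had a Spearman rho of 0.96, where loci are not independent replicates. The balance of higher and lower loci depended on the scaling. On the deposited RPKM values, whose median log2 fold was 0.43 against 0.01 on the TMM scale, 780 of the same loci were at least 2-fold higher and 239 at least 2-fold lower in the W-type. With totals that left out the 10 most abundant loci, the median was 0.22 and 390 loci were higher and 349 lower. Lower loci thus made up 74.2% of the changed loci on the TMM scale, 47.2% without the 10 loci and 23.5% on the RPKM scale. Of the loci beyond 2-fold on the TMM scale, 166 of the 171 higher and 236 of the 492 lower loci were beyond it under all 6 scalings, of which the largest shifts were towards the W-type.

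**Figure D1:**
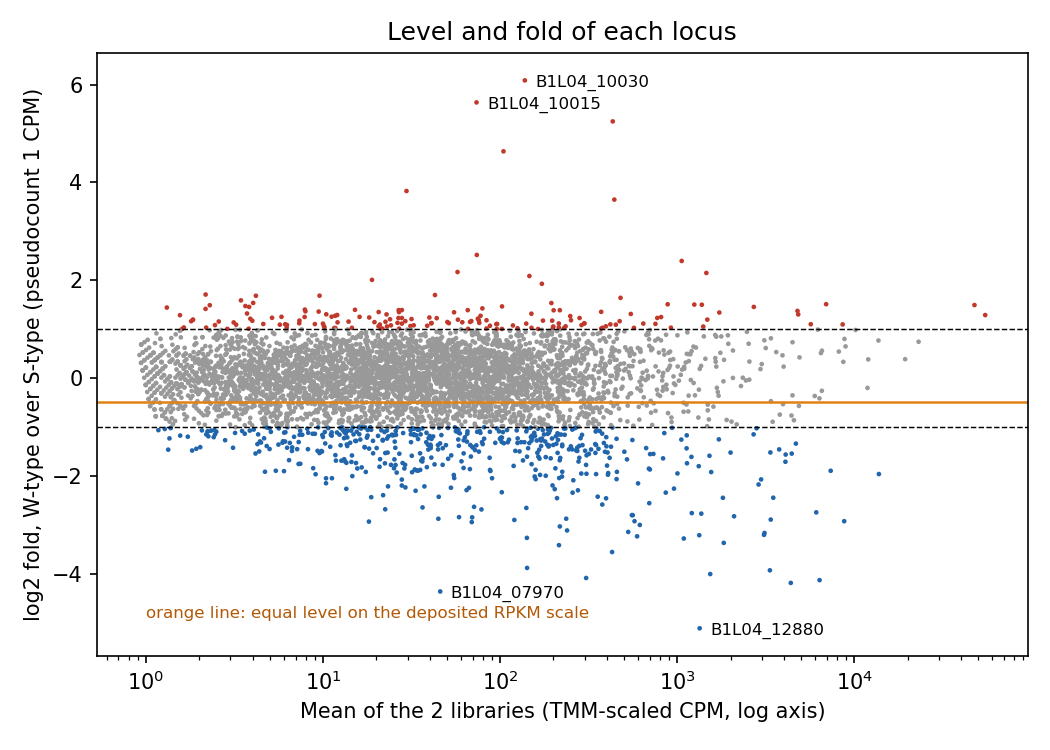
Each point is 1 of 4987 loci, placed by its mean level in the 2 libraries (TMM-scaled CPM, log axis) and its log2 fold, W-type over S-type. Dashed lines mark 2-fold, with 171 loci above (red) and 492 below (blue), the 4 labelled loci have the largest folds, and the orange line marks where a locus had equal RPKM in both libraries, 0.48 below zero for ratios without a pseudocount.

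The largest folds higher in the W-type were at loci with few reads in the S-type. Locus B1L04_10030, with a coding length of 393 nt, had 25 counts (3.03 CPM) in the S-type and 3322 counts (273 CPM) in the W-type, a ratio of 90.0 with a 95% counting interval of 60.8 to 139. Locus B1L04_10015, 300 nt long, had 16 counts in the S-type and 1768 in the W-type, a ratio of 74.8 with an interval of 45.9 to 131. In the other direction, locus B1L04_12880, 2751 nt long, had 2604 CPM in the S-type and 74.5 CPM in the W-type, which is 34.9 times lower with an interval of 32.7 to 37.4. Locus B1L04_07970, 180 nt long, had 88.5 CPM in the S-type and 3.37 CPM in the W-type, which is 26.3 times lower with an interval of 19.2 to 36.9. The ratios of the deposited RPKM values at these loci were 125 and 104 in favour of the W-type and 25.1 and 18.9 in favour of the S-type. Reads that fit several near-identical loci could be counted in more than one way, and how they were treated is not given in the sources used here.

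Part of the changed loci, 15.7%, stood in runs of neighbours in the locus tag order. Runs of at least 4 consecutive loci, all at least 2-fold changed in one direction, held 22 loci in 5 runs higher in the W-type and 82 loci in 16 runs lower in the W-type. This balance turned with the scaling, to 143 loci in runs higher and 29 in runs lower on the deposited RPKM, and to 39 and 65 with totals that left out the 10 most abundant loci. In 1000 random orders of the same folds, such runs held a median of 0 and at most 11 loci, against 104 observed on the TMM scale. The largest contrast was a run of 4 loci ending at B1L04_10015, with 275 counts in the S-type and 15182 in the W-type, 37.4 times higher with an interval of 33.2 to 42.3. The tags between this run and B1L04_10030 were 2 loci with at most 2 reads in either library. The longest run higher in the W-type spanned 6 loci and 9240 nt of coding length, at 6400 CPM in the S-type and 19561 CPM in the W-type, a ratio of 3.06 with an interval of 3.03 to 3.09.

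Among the runs lower in the W-type, 1 run of 8 loci with 13002 nt of coding length stood out by abundance. It took 4.41% of all counts in the S-type library and 0.610% in the W-type library. It was 7.31 times lower in the W-type with an interval of 7.25 to 7.36. Its single loci were 4.77 to 11.7 times lower, with the pseudocount of 1 CPM. A second run of 8 loci, with coding lengths of 180 to 570 nt, was 2.46 times lower. A pair of runs of 4 loci each were 7.74 and 7.73 times lower, and a run of 5 short loci, at most 369 nt long, was 7.05 times lower. All runs lower in the W-type together held 10.4% of the S-type counts and 2.11% of the W-type counts, and the runs higher in the W-type held 1.42% and 4.06%. The RPKM scale moves folds towards the W-type, and on it 5 of the 16 lower runs had every locus at least 2-fold lower. The run of 8 loci with the high abundance was among these 5, at 5.25 times lower. On the same scale the pair of runs of 4 loci were 5.56 and 5.55 times lower, each with 3 loci at least 2-fold lower. The run of 5 short loci was 5.06 times lower, with 4 such loci. The second run of 8 loci was only 1.77 times lower, with 2 such loci.

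**Figure D2:**
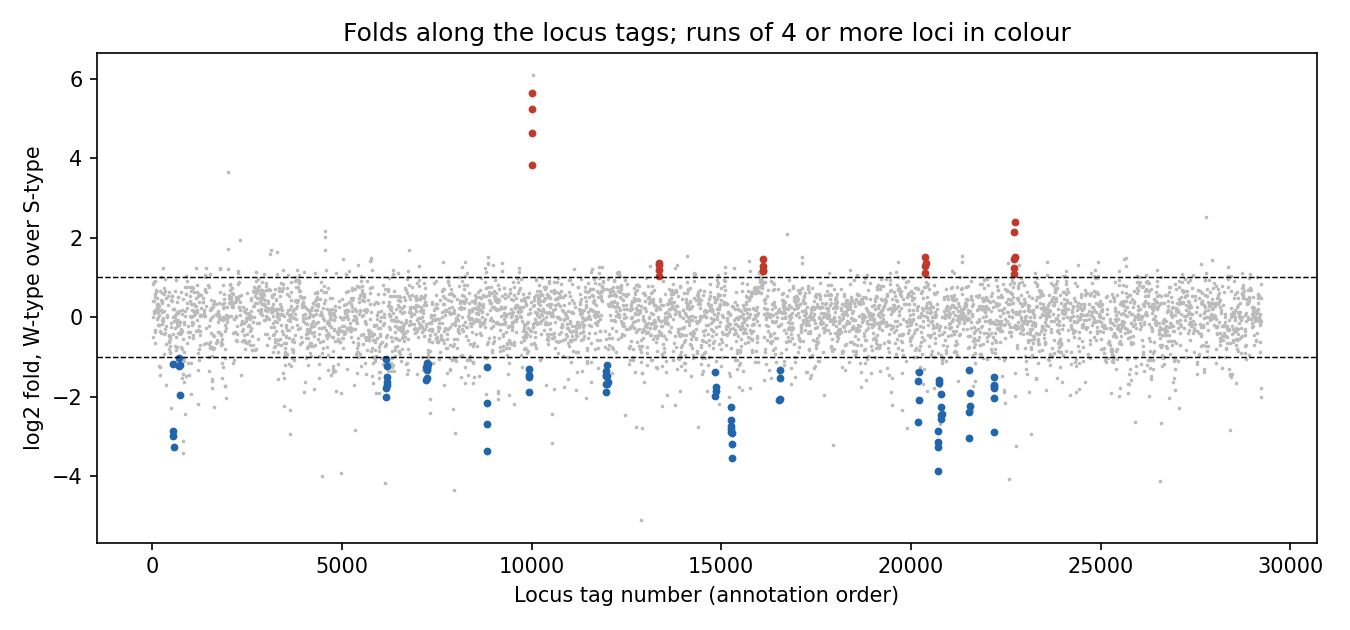
The log2 fold, W-type over S-type, of 4987 loci (grey points) is plotted against the number in the locus tag, which gives the annotation order. Loci in runs of at least 4 neighbours are coloured, with 22 loci in 5 runs higher in the W-type (red) and 82 loci in 16 runs lower (blue) on the TMM scale, against 143 and 29 loci on the deposited RPKM.

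The most abundant loci by read count took a larger part of the W-type library, mainly through 2 consecutive loci. The 10 most abundant loci held 17.4% of the counts in the S-type (95% Wilson interval 17.38 to 17.44) and 27.9% in the W-type (27.88 to 27.93), and 5 loci were in the top 10 of both. A pair of consecutive loci of 2214 and 2247 nt ranked 1 and 2 in both libraries. Ranks here are by read count, without regard to length. On the deposited RPKM a locus of 354 nt lay above both, at 13061 in the S-type and 23746 in the W-type. The locus of 2214 nt had 6394 and 21778, and that of 2247 nt had 4944 and 19406.5. In the S-type, loci of 462, 654 and 1083 nt also lay above both, at 11590, 11399 and 7076. In the W-type, the locus of 654 nt, at 20797, lay above that of 2247 nt. The loci of the pair were 2.45 and 2.82 times higher in the W-type on the TMM scale. Together they held 5.65% of the S-type counts and 14.9% of the W-type counts. Choosing loci by their level in 1 library favours loci that are higher in it. Of the 10 most abundant loci of the S-type, 5 were at least 2-fold lower in the W-type, by 3.71 to 17.5 times. The largest of these differences was at a locus of 462 nt, which ranked 8 in the S-type at 12044 CPM and 190 in the W-type at 690 CPM. A locus of 2442 nt that ranked 3 in the S-type and 22 in the W-type was 3.88 times lower. On the TMM scale, the other loci among the 5 most abundant of either library lay within 2-fold. Loci of 1083 and 654 nt, ranked 4 and 5 in the S-type and 3 and 4 in the W-type, were 1.68 and 1.31 times higher in the W-type, and a locus of 1383 nt, ranked 12 in the S-type and 5 in the W-type, was 1.71 times higher. On the TMM scale, none of the 10 most abundant loci of the W-type was 2-fold lower there, and 3 were 2-fold higher. On the deposited RPKM, which moves folds towards the W-type, more of these 10 loci were over 2-fold higher. The locus of 1083 nt stood at 7076 in the S-type and 16521 in the W-type. That of 1383 nt stood at 3252.5 and 7726. Of the 10 most abundant S-type loci, the 5 lower ones stayed over 2-fold lower on that scale. These 5 loci are not all separate from the runs above. Those of 3312 and 2235 nt were members of the abundant run of 8 loci. That of 2442 nt held 180504 of the 181754 S-type counts of another lower run, of 4 loci.

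Loci 2-fold lower in the W-type were most frequent at the highest levels. With loci split into 10 bins by mean level, 98 of the 499 loci in the highest bin and 90 of the 499 in the next were 2-fold lower. In the other 8 bins 22 to 54 loci were lower, with no steady rise with level. In the same bins, counted again after the data were seen, the highest bin and the next held 69 and 37 lower loci on the RPKM scale, against 10 to 22 in the others, and 86 and 62 with totals without the 10 most abundant loci, against 17 to 35. The pseudocount shrinks folds most in the lowest bins. Loci 2-fold higher on the TMM scale numbered 36 in the highest bin, 21 in the next and 9 to 21 in the others. In the highest bin the 69 lower loci on the RPKM scale stood against 121 higher, and the 86 lower loci without the 10 most abundant loci against 68 higher, so which direction was in excess there depended on the scaling. Of 798 loci with a coding length under 300 nt, 144 (18.0%) were 2-fold lower and 18 (2.26%) 2-fold higher. Of 3537 loci between 300 and 1500 nt, 299 (8.45%) were 2-fold lower and 125 (3.53%) 2-fold higher. The median log2 fold of the short loci was -0.26, below all of 10000 random lists of the same size matched on level, of which 95% had medians between -0.04 and 0.05. On the RPKM scale that median was 0.14, above zero but below the 0.43 of all loci, so the sign of the short loci changed with the scaling. On the TMM scale the median of the loci between 300 and 1500 nt was 0.04, above the matched range of -0.02 to 0.03. That of 558 loci between 1500 and 3000 nt was 0.06, above the matched range of -0.08 to 0.05. The random lists drew loci independently, while folds of neighbouring loci were correlated, so the ranges may be too narrow. The 3537 loci were also most of the pool from which lists were drawn. Margins this small therefore do not set these longer classes apart. The 94 loci of at least 3000 nt had a median of 0.09, within the range of matched lists from -0.23 to 0.16, with 6 loci (6.38%) 2-fold higher and 14 (14.9%) lower.

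The libraries also differed in how many reads were counted at the listed loci. Counts and RPKM values together gave the read totals used as RPKM denominators, 18537594 reads in the S-type and 19668142 in the W-type, inferred values for which the kinds of reads included are not given in the sources used here. The listed loci held 44.7% of that total in the S-type and 61.6% in the W-type. The log2 ratios of W-type over S-type without a pseudocount were higher on the RPKM scale than on the TMM scale by 0.48, with an SD of 0.00022 over 3196 loci with an RPKM of at least 10 in both libraries.

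**Figure D3:**
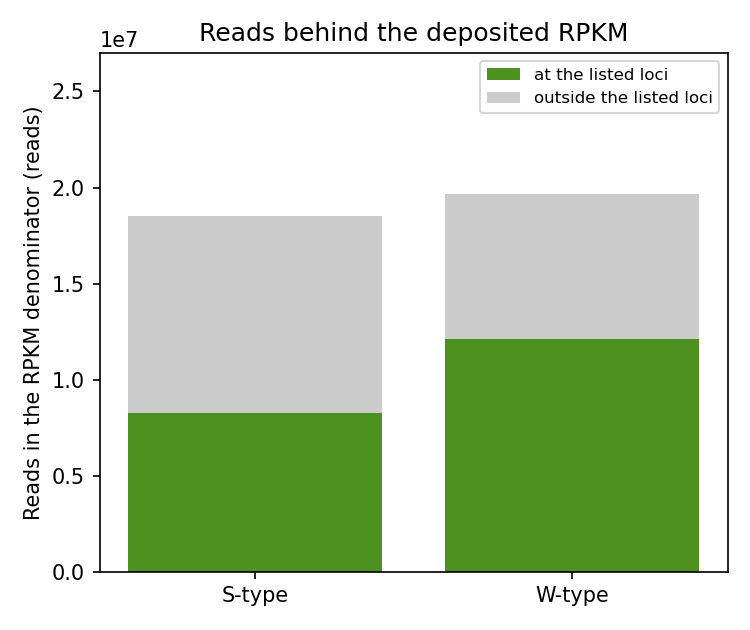
Bars show the reads in the RPKM denominator of each library (y axis, reads), split into reads counted at the listed loci (green) and all others (grey). The listed loci held 44.7% of 18537594 reads in the S-type and 61.6% of 19668142 in the W-type.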

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

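Of the tests in this part, the one on ribosomal RNA or other organisms was chosen after the result was seen. Reads that entered the RPKM denominator but lay outside the listed loci are not part of the fold comparison on TMM-scaled counts, and they enter the RPKM scale only through its totals. They made up 55.3% of the denominator in the S-type (about 10246247 reads) and 38.4% in the W-type (about 7561271 reads), obtained by subtracting the counts from the inferred denominators.

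Reads from genomic DNA spread over all loci would raise the quietest loci of the S-type. The median RPKM of the 10% of loci with the lowest RPKM was 1.70 in the S-type and 2.51 in the W-type, a ratio of 0.677. The RPKM scale lowers S-type values at all loci, with a median log2 fold of 0.43 towards the W-type. A ratio below 1 at the quietest loci therefore does not decide whether such reads were a source. Their level does set a bound. Spread evenly, such reads could add no more than about 1.70 RPKM per locus in the S-type, the level of the quietest loci. The 5795 listed loci summed to 481065 RPKM in the S-type, so at these loci such reads would be a small part. Their part of the 55.3% depends on the length outside the loci, which is not known here. Residual ribosomal RNA, other bacteria in the cultures, reads between genes and loci not analysed here may all add to the 55.3%, and these cannot be told apart, because the tables hold only reads at the listed loci. A difference between the morphotypes in how much of their RNA is messenger RNA stays open and untested.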

How the results depend on the processing

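The RPKM scale, the centred scales and all counts of loci in runs were chosen after the result was seen. The numbers of loci 2-fold higher and lower (171 and 492) stayed within 1.5 times under a pseudocount of 0.1, no filter, a minimum of 100 reads, DESeq2 factors, upper-quartile scaling and plain totals, with ranges of 151 to 239 and 427 to 569. They became 75 and 296 with a pseudocount of 10 CPM, by construction, and 12 and 83 with a 4-fold rule. With totals that left out the 10 most abundant loci they became 390 and 349, as the median log2 fold moved to 0.22. With the deposited RPKM they became 780 and 239. Centring on the median undoes these shifts by construction, and gave 182 and 491 for the RPKM and 183 and 511 for the totals without the 10 loci. The smallest log2 fold of B1L04_10015 was 3.70 and that of B1L04_10030 was 4.44, and B1L04_07970 came to -2.88, all with a pseudocount of 10 CPM. The share of counts in the top 10 loci became 17.1% in the S-type and 23.3% in the W-type when summed RPKM was used. With runs of at least 3 loci, 34 loci were in runs higher and 127 in runs lower, and with a 4-fold rule 4 and 12. The 22 and 82 loci in runs became 143 and 29 with the deposited RPKM, 39 and 65 with totals without the 10 loci, and 17 and 48 with a pseudocount of 10 CPM. Alternatives for gene lists were not run, as no list could be matched. No paired analysis was possible because each morphotype had 1 library, and no library could be left out. Depth limits the quiet loci. The 808 loci under 20 reads allow no statement on change.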

Other observations

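Tests on the random order of loci and on the RPKM denominator were chosen after the result was seen. The tests at 3 tags and with trends removed were set after the adjacent-tag correlation had been seen, but before their own results. No locus was well covered in one morphotype and empty in the other. At 192 loci both libraries had 0 counts. The 80 loci with reads only in the W-type had at most 12, and the 39 loci with reads only in the S-type had at most 9. Loci whose length was not a multiple of 3 numbered 159 and did not stand apart, with 7 loci 2-fold higher, 18 lower and a median log2 fold of 0.05, at the 79.7th percentile of matched lists.

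Neighbouring loci changed together: the correlation of log2 folds, across loci, was 0.44 between adjacent tags, 0.26 at 2 tags, 0.17 at 3 tags and 0.05 at 10 tags, where random orders gave at most 0.05 at each of these distances. A random order of the changed loci is argued against by the 104 loci in runs, where random orders reached 11. Reads shared between adjacent loci are argued against as the whole of the pattern by the correlation of 0.17 at 3 tags, where random orders reached 0.04. Such reads may still add to the 0.44 at adjacent tags. Similar level or length of neighbours is argued against too, because the correlation was still 0.44 after the trends on level and length were removed. Joint transcription of gene clusters may account for these runs, as a hypothesis, and it stays untested here without strand and coordinates. Whether the morphotype or another difference between these 2 cultures set the levels stays open with 1 library each.

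More loci were lower than higher in the W-type, by a ratio of 2.88. Removing the trend of the fold on coding length left a ratio of 2.45, which argues against a length bias as the whole of it. Leaving the 10 most abundant loci out of the totals gave 0.895, and the RPKM denominators gave 0.306, so the direction of the imbalance may come from where equal expression is set. On the TMM scale 83 loci were 4-fold lower and 12 were 4-fold higher. Whether total messenger RNA per cell differed is not known from these data, and a difference between the morphotypes stays open and untested.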
